A study of Homo sapiens with 13 samples.

How the data were processed

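PolyA-selected RNA was sequenced from MCF10A-Src cells at 0, 4, 12 and 36 h of tamoxifen and from parental MCF10A cells 72 h after transduction, per the labels' protocols. Base calling with CASAVA 1.4, alignment to hg19 with TopHat and quantification with Cuffdiff were named in the submitters' processing notes; the TopHat and Cuffdiff versions, the annotation and the strand setting were not given in the sources used here. Each experiment had 1 deposited table of 38369 gene rows, in which a row was either a coding gene or an assembled long intergenic RNA (lincRNA). Per the file headers, the authors' Cuffdiff tables hold for each gene and library an estimated count of fragments before scaling. They also hold FPKM (fragments scaled by transcript length and library size) as deposited, which Cuffdiff had scaled across libraries. The authors' deposited calls tables hold a log2 fold change, a p-value and a q-value for each pair of conditions. In the time-course calls table the deposited log2 column reached values too large for a log2 fold change, so it was read as a score and used for its sign, except for the LINC00520 row.

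Of the 13 samples, 11 were matched to columns by name. The 2 samples of a control lincRNA matched no condition name and were not analysed here, so LINC00520 was compared with untransduced cells alone. A further 7 libraries in the over-expression table, whose condition names begin like that of the LINC00520 libraries but match no label, were not used in any step. The replicate number of a library was used as a name. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The files do not use the name LINC00520. Its row was taken as linc-TBPL2-2, the lincRNA lying between KTN1 and PELI2 on chromosome 14, where LINC00520 (also C14orf34) lies in the reference annotation. All coordinates are 1-based hg19 positions from the files, and none were taken from the reference, which was of another build.

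The plan written before the data were examined assumed FPKM alone and named limma on log2(FPKM + 1). The tables also held estimated counts, for which edgeR's quasi-likelihood (QL) test is the fitting test, so edgeR was made the main test before any model was fitted and limma was kept as an alternative. Estimated counts were rounded to whole numbers; 92.4% to 99.9% of values in a library were already whole. Genes entered a fit with an FPKM of 1 or more in at least 2 libraries (over-expression) or at least 1 library (time course), and a Cuffdiff status of OK in every library of the fit; 22 and 59 rows lacked that status. This left 12790 and 15572 genes. Counts were scaled by edgeR's TMM factors, and estimateDisp, glmQLFit and glmQLFTest were run with 1 coefficient per group, all libraries of an experiment sharing 1 estimate of the spread. P-values were 2-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Standard errors were the absolute log2 fold change divided by the square root of the QL F statistic, and levels are edgeR's CPM after TMM scaling. The common coefficient of variation between replicates was 0.0249 in the over-expression experiment (3 residual degrees of freedom) and 0.162 in the time course (2 residual degrees of freedom). The 0 h and 12 h groups had 1 library each and were assumed to vary like the 4 h and 36 h pairs. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

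Library depth ranged from 12.6 to 52.3 M fragments. Between replicates, the median ratio of the chi-square statistic of a gene's counts to its value under counting noise was 1.23 to 1.72 in the over-expression groups, 3.47 at 36 h and 10.99 at 4 h. The mean of the statistic over genes was 1.39 to 2.62 in the over-expression groups, 45.49 at 4 h and 54.62 at 36 h. By the mean the 36 h pair thus did not agree better than the 4 h pair. No pair was close enough to be counted as 1 library. Same-numbered libraries did not deviate together across genes (correlations -0.028, -0.041 and 0.078), so the numbers did not pair them. A fold against a group with no fragments is given as a lower bound, computed with 3 fragments over the group. Where a group had 1 to 3 fragments, the ratio is given with an exact 95% Clopper-Pearson interval that covers counting error only.

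Before the data were examined, 29 gene lists, the rule for named genes and most alternatives were fixed. The rule took LINC00520, SRC and STAT3; the 8 largest rises and 8 largest falls (5 each way against 0 h) among called genes with FPKM of 1 or more in the higher group and libraries that did not overlap; up to 4 members with the smallest p of each list that moved; and genes within 1 Mb of LINC00520. Rows with no symbol or several symbols were passed over in the second part. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, over 27 lists; endothelial markers had 1 and 2 measured members and the mitochondrial genome 0, and were left out. Alternatives were limma with pseudocounts of 1, 0.1 and 5, without its trend, after quantile normalization and after median-ratio rescaling; edgeR with no filter and with an FPKM of 5 or more; the replicate number as a block; each replicate left out; and the authors' deposited calls. The plan paired its filter, replicate and block alternatives with limma; they were run with edgeR. Fitting only the 4 h and 36 h libraries was also planned and run. DESeq2, edgeR's own count filter, median-ratio and upper-quartile factors and no scaling beyond the library total were added after seeing the data. The gene sets carried from the time course into the over-expression experiment follow the plan (all genes called at a time); sets limited to changes of at least 2-fold had been looked at first. The overlap counts of calls between the experiments were not in the plan.

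The tests were run on simulated data with known changes, after the first fit of the real data. In the simulated over-expression experiment (12790 genes), edgeR recovered 70% of genes changed 1.2-fold, 92% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, with 11 unchanged genes called. In the simulated comparison of 36 h with 4 h (15572 genes) it recovered 0%, 6%, 54% and 92% at those sizes. At 2-fold and 4-fold it recovered 36% and 90% for 4 h against 0 h, 12% and 86% for 12 h against 0 h, and 20% and 96% for 36 h against 0 h. In 1 simulation per comparison, a set of 20 genes changed 1.5-fold had an unadjusted camera p of at most 7.46e-12. For 36 h against 4 h, a set of 20 unchanged genes had an unadjusted camera p of 0.0136 and fry p of 0.007. Camera with an estimated correlation gave it 0.115, so list calls in this comparison can arise without a change. In the other comparisons the unchanged set had a camera p of 0.179 or more. The simulated genes were drawn independently, while the estimated correlation of the cell cycle list was 0.566 with over-expression. The simulations therefore cannot show how often camera at the preset correlation calls unchanged lists in these data. limma on log2(FPKM + 1), the planned test, recovered 0% of the 4-fold genes in each of the 4 simulated time-course comparisons and 100% in the over-expression one. Each simulation changed only 50 genes at each size and the set of 20, fewer than edgeR called in the data. Where many genes change the adjusted threshold is less strict, so these recoveries may understate sensitivity. In the data the same limma test called 2331 genes higher and 2323 lower for 36 h against 4 h.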

Results

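The data were polyA RNA-seq libraries of MCF10A, an immortalised, non-tumorigenic human breast epithelial line. In MCF10A-Src cells, a derivative in which tamoxifen switches on an introduced Src kinase, 1 library was made at 0 h, 2 at 4 h, 1 at 12 h and 2 at 36 h. Their depths were 52.3 M fragments at 0 h, 18.5 and 23.3 M at 4 h, 26.6 M at 12 h, and 24.0 and 12.6 M at 36 h. In parental MCF10A cells, 3 untransduced libraries (36.4, 30.3 and 22.9 M fragments) and 2 libraries transduced with LINC00520 (25.2 and 23.4 M) were used. The study asked when the lincRNA LINC00520 is induced as Src transforms these cells and what its over-expression changes.

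LINC00520 (the row linc-TBPL2-2, XLOC_004884, chromosome 14, 56243909 to 56263392, hg19) was measured first. Untransduced parental cells held 0.142 ± 0.0558 CPM (SD, n = 3; 5, 6 and 2 fragments) and transduced cells 46.1 ± 0.166 CPM (SD, n = 2; 1122 and 1031 fragments). In MCF10A-Src cells it stood at 1.59 CPM at 0 h, 1.25 ± 0.44 CPM at 4 h (SD, n = 2), 14.7 CPM at 12 h and 182 ± 28.2 CPM at 36 h (SD, n = 2). By edgeR's QL test with Benjamini-Hochberg adjustment, 36 h was 148-fold above 4 h (log2 7.21, SE 0.286, adjusted p = 6.61e-06) and 114-fold above 0 h (adjusted p = 3.78e-05). By the same edgeR test 12 h was 9.18-fold above 0 h (log2 3.20, SE 0.335, adjusted p = 0.0019). The 4 h level was not past the test against 0 h (log2 -0.38, SE 0.335, edgeR adjusted p = 0.529). Among 3990 lincRNA rows tested in the time course, it ranked 10 by log2 fold change from 4 h to 36 h and 113 by level at 36 h. With limma on log2(FPKM + 1) the 12 h rise was 2.00 on the log2 scale and not past the test. Folds from the deposited FPKM were larger than from fragments, 582 against 304 in the over-expression experiment and 663 against 148 for 36 h over 4 h. The order of levels between the experiments also depended on the unit. In deposited FPKM the over-expression libraries held 225.2 and 224 and the 36 h libraries 70.7 and 105.5, the reverse of the order in CPM. Levels were therefore compared only within an experiment.

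**Figure D1:**
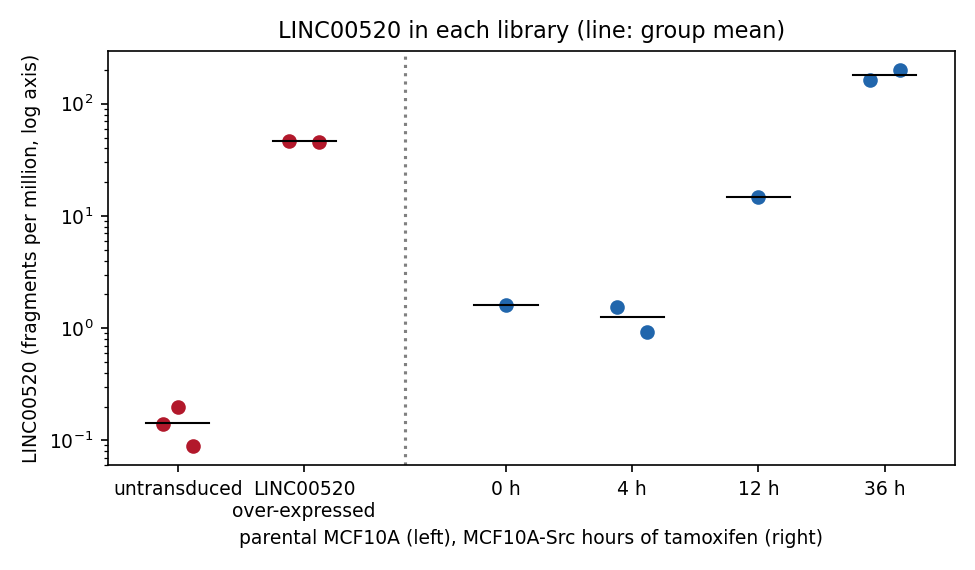
LINC00520 level in each library (CPM, log axis), by group; points are libraries and lines are group means. Transduced cells averaged 46.1 CPM against 0.142 CPM in untransduced cells, and the time course went from 1.59 CPM at 0 h to 182 CPM at 36 h. Levels are to be compared within an experiment only, since the deposited FPKM put over-expression above 36 h.

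LINC00520-transduced cells were compared with untransduced cells. After LINC00520 itself (304-fold; log2 8.25, SE 0.127, edgeR adjusted p = 4.19e-24), the largest rises among named genes with more than 3 fragments in each group were of POSTN and ID2. POSTN, the matricellular protein periostin, went from 2.00 ± 0.763 (SD, n = 3) to 19.1 ± 1.26 CPM (SD, n = 2). ID2, an inhibitor of helix-loop-helix transcription factors, went from 1.12 ± 0.316 to 6.91 ± 0.762 CPM. All 34 measured cell cycle genes rose and all 38 measured ribosomal protein genes fell, the first by a median of 0.53 and the second with a median of -0.20 on the log2 scale (adjusted p = 0.102 and 0.307 with an estimated correlation). After quantile normalization 23 of the 38 ribosomal protein genes were lower by limma, with a median of -0.07. The authors' deposited log2 values kept a median of -0.20, with 0 of them called. Most changes were small: 3218 genes were higher and 3178 lower of 12790 tested, with a median absolute change of 0.244, and 57 and 105 of them changed at least 2-fold.

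POSTN (chromosome 13, 38136720 to 38183563) rose 9.08-fold (SE 0.133 on the log2 scale) and ID2 (chromosome 2, 8806619 to 8824609) 5.95-fold (SE 0.168), with edgeR adjusted p = 2.37e-15 and 7.68e-12. The other large rises were of linc-HOXC13-AS (log2 1.91, SE 0.223; at the position of HOXC13, from which it cannot be separated without strand), the protease inhibitor SPINK6 (1.86, SE 0.218), the interferon-induced IFI27 (1.81, SE 0.34) and the inflammasome sensor NLRP3 (1.79, SE 0.164). HBB, the beta globin gene, had 28 fragments in transduced and 3 in untransduced libraries, a ratio of 17.7 (95% interval 5.47 to 91). TJP3, a tight junction scaffold, fell by 2.54 (SE 0.173), the surfactant gene SFTPB by 2.33 and STAC2 by 2.23. Also lower were the chemokine receptor CXCR4 (-2.21), the inositol phosphate kinase IP6K3 (-2.20) and BBOX1, of carnitine synthesis (-1.98). STAT3 had a log2 fold change of -0.22 (SE 0.0296, edgeR adjusted p = 9.77e-07), and SRC was not past the test (0.02, SE 0.0524, edgeR adjusted p = 0.725).

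Among the 34 cell cycle genes, RRM2, which makes deoxynucleotides, and the origin licensing factor CDC6 each rose by 1.08, the replication clamp PCNA by 0.69 and the helicase subunit MCM4 by 0.65 (camera adjusted p = 4.93e-51, and adjusted p = 0.102 with an estimated correlation). Of 14 heat shock genes 11 rose and 0 fell, HSPH1 by 0.59 and HSP90AA1 by 0.45 (camera adjusted p = 5.55e-07, and adjusted p = 0.0781 with an estimated correlation). Of 25 MYC and ribosome biogenesis genes 19 rose and 1 fell, NOP56 by 0.45 and LYAR by 0.40 (camera adjusted p = 1.62e-05, and adjusted p = 0.344 with an estimated correlation). The ribosomal protein genes had changes from -0.26 to -0.08, with RPS2, RPL19 and RPL28 at -0.26 (camera adjusted p = 2.46e-12, and adjusted p = 0.307 with an estimated correlation). Of 7 replication histone genes, which polyA selection captures poorly, 5 fell and 0 rose, HIST1H2AC by 0.56 (camera adjusted p = 0.037, and adjusted p = 0.307 with an estimated correlation).

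Of 16 TGF-beta target genes 10 rose and 2 fell: ID3 rose by 1.41 and ID1 by 0.91 (camera adjusted p = 8.71e-09, and adjusted p = 0.0781 with an estimated correlation). The list does not record in which direction TGF-beta moves each member. Its counts, here and in the time course, are therefore no measure of TGF-beta signalling. Of 11 mesenchymal genes 6 rose and 2 fell, fibronectin (FN1) rising by 1.61 and vimentin (VIM) falling with a log2 change of -0.17 (camera adjusted p = 8.19e-05, and adjusted p = 0.102 with an estimated correlation). Of 20 basal keratinocyte and adhesion genes 13 rose and 1 fell, KRT14 by 1.44 and KRT6A by 0.54 (camera adjusted p = 1.76e-10, and adjusted p = 0.0781 with an estimated correlation). Of 21 epithelial adhesion genes 15 fell and 3 rose, EPCAM with -0.74 and the luminal keratin KRT8 with -0.70 (camera adjusted p = 9.14e-08, and adjusted p = 0.102 with an estimated correlation).

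Of 18 FOXO target genes, which PI3K and AKT signalling holds down, 13 fell and 0 rose, PDK4 with -1.31, BCL6 with -1.06 and TXNIP with -0.71 (camera adjusted p = 5.71e-08, and adjusted p = 0.123 with an estimated correlation). Of 19 NRF2 genes 12 fell and 2 rose, the reductase AKR1C2 with -1.05 and ferritin heavy chain FTH1 with -0.57 (camera adjusted p = 1.38e-07, and adjusted p = 0.102 with an estimated correlation). Of 17 IL-6/STAT3 genes 11 fell and 2 rose, IL6R with -0.95 and CEBPD with -0.64 (camera adjusted p = 1.39e-07, and adjusted p = 0.0781 with an estimated correlation). Of 20 NF-kB genes 9 fell and 2 rose, the superoxide dismutase SOD2 with -0.98 and TNFAIP2 with -1.09 falling and IL1A rising by 0.38 (camera adjusted p = 0.00146, and adjusted p = 0.307 with an estimated correlation). Of 21 ATF4 genes 16 fell and 2 rose, DDIT4 with -0.56 (camera adjusted p = 4.14e-04, and adjusted p = 0.166 with an estimated correlation). Of 19 p53 targets 11 fell and 3 rose, GDF15 with -0.79 (camera adjusted p = 0.0147, and adjusted p = 0.166 with an estimated correlation). Adjusted over the list alone, heat shock held 13 higher and 1 lower and p53 3 higher and 12 lower, and the counts of the other 13 lists named so far were the same as over all genes.

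The other 12 tested lists were not past camera. Of 24 immediate early and ERK feedback genes 4 were higher and 10 lower (5 and 10 adjusted over the list alone), with FOSL1 at 0.66 and FOS at -0.65. The matrix and protease list had 7 higher and 5 lower of 16, cornification 6 and 3 of 12, cholesterol synthesis 5 and 4 of 21, hypoxia and glycolysis 7 and 4 of 21, and the interferon response 3 and 7 of 23. The unfolded protein response had 7 higher and 2 lower of 19, YAP/TAZ targets 5 and 3 of 11, estrogen receptor targets 3 and 3 of 10, and Src, STAT3 and PI3K pathway components 6 and 7 of 21. Of 4 measured immune or blood cell markers 1 was higher and 1 lower, and of 4 fibroblast markers 1 was higher. Within 1 Mb of LINC00520, 4 of 14 measured genes were higher and 3 lower, with WDHD1 at 0.58 (SE 0.0447), DLGAP5 at 0.43 (SE 0.0366) and LGALS3 at -0.32 (SE 0.0343) having the smallest p. Of all genes tested 50% were called in this comparison, so these counts do not set the region apart. The comparison cannot separate LINC00520 from transduction, since the 2 control lincRNA libraries were not analysed here.

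**Figure D2:**
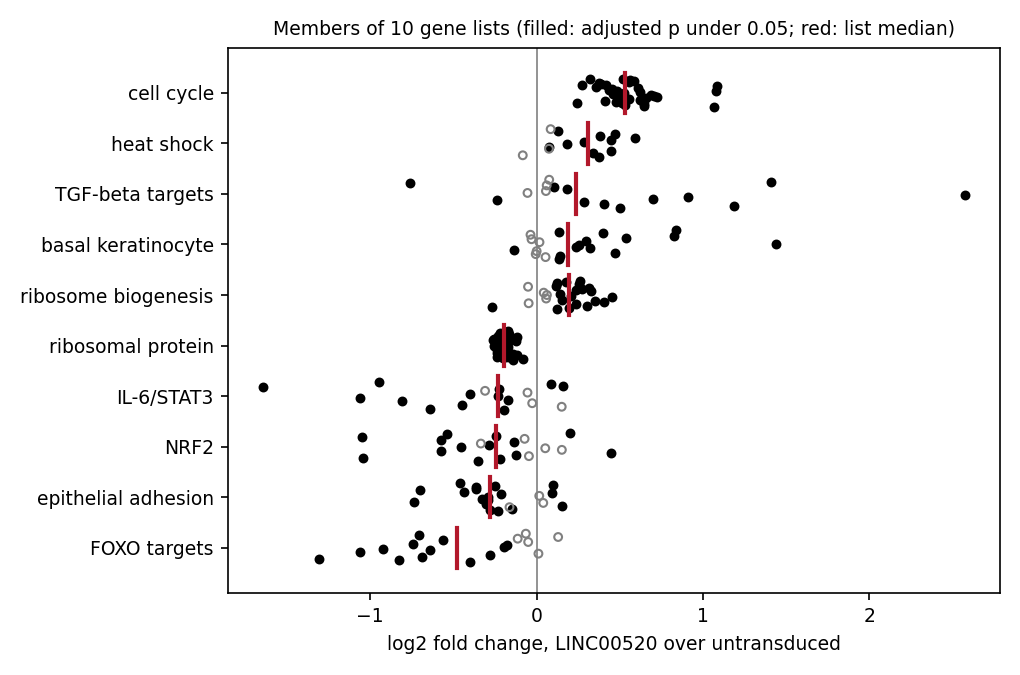
Log2 fold change (x axis, LINC00520 over untransduced) of each measured member of 10 gene lists (y axis); filled points have an edgeR adjusted p under 0.05 and red bars mark list medians. All 34 cell cycle genes lie to the right of 0 and all 38 ribosomal protein genes to the left, with medians of 0.53 and -0.20.

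The comparison of 36 h with 4 h of tamoxifen, the only one in the time course with replicates on both sides, asked what changes late. No sample was kept without tamoxifen for 4, 12 or 36 h. In every time-course comparison an effect of Src activation and one of time in culture therefore cannot be told apart. The germline helicase gene TDRD9 went from 1 fragment at 4 h to 88.4 ± 5.25 CPM at 36 h (SD, n = 2), a ratio of 3840 (95% interval 688 to 152000). The protease gene GZMB went from 1 fragment to 44.5 ± 8.47 CPM, a ratio of 1820 (95% interval 327 to 72000). S100A8 and S100A9, which encode the calprotectin subunits, rose by 5.06 and 4.69 on the log2 scale (SE 0.231 and 0.211). The chemokine gene CCL2 fell at least 92.5-fold, to 0 fragments. Of 17 measured FOXO targets 12 were higher, and of 22 epithelial adhesion genes 13 were lower and 1 higher (adjusted p = 0.285 for each with an estimated correlation).

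By edgeR, 2930 genes were higher and 3200 lower at 36 h of 15572 tested, 1570 and 1540 of them by at least 2-fold. Other large rises from 0 fragments at 4 h were of linc-LSAMP-5 (at least 70.1-fold), the atypical GTPase RHOH (at least 68.7-fold), IGFN1 (at least 59.1-fold), RGS8 (at least 35.6-fold) and the fibrinogen chain FGG (at least 33.5-fold). The neighbouring chemokine genes CXCL10 and CXCL11, whose deposited rows share a locus, were at least 26.2-fold and 24.4-fold lower at 36 h. linc-SCARA3-AS, which cannot be separated from SCARA3 without strand, and linc-RFC3 were at least 8.86-fold and 3.34-fold lower. KRT75, GALNT9 and CLDN16, with 2, 1 and 1 fragments at 36 h, were lower by ratios of 108 (95% interval 29.6 to 895), 94.8 (16.7 to 3770) and 62 (10.8 to 2480). SRC had a log2 fold change of -0.90 (SE 0.241, edgeR adjusted p = 0.0208), and STAT3 was not past the test (0.08, SE 0.154, edgeR adjusted p = 0.701).

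Of 18 matrix and protease genes 13 rose and 3 fell, the metalloprotease ADAM19 by 5.37, the cathepsin CTSL1 by 5.23 and the integrin ITGA5 by 3.09 (camera adjusted p = 9.06e-05, and adjusted p = 0.285 with an estimated correlation). Of 17 FOXO targets 12 rose and 0 fell, KLF9 by 4.86, CCNG2 by 4.40 and KLHL24 by 2.82 (camera adjusted p = 9.06e-05, and adjusted p = 0.285 with an estimated correlation). Of 25 hypoxia and glycolysis genes 15 rose and 3 fell, NDRG1 by 2.95 and the glucose transporter SLC2A3 by 2.47 (camera adjusted p = 0.00184, and adjusted p = 0.496 with an estimated correlation). Of 38 ribosomal protein genes 20 rose and 0 fell, RPLP1 by 1.44 and RPL28 by 1.39 (camera adjusted p = 2.45e-05, and adjusted p = 0.663 with an estimated correlation). Of 22 epithelial adhesion genes 13 fell and 1 rose, the claudins CLDN1 with -5.44 and CLDN4 with -3.48 and the transcription factor OVOL1 with -4.32 (camera adjusted p = 9.06e-05, and adjusted p = 0.285 with an estimated correlation). Of 19 NRF2 genes 14 fell and 1 rose, the quinone reductase NQO1 with -2.31 (camera adjusted p = 2.45e-05, and adjusted p = 0.359 with an estimated correlation).

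Of 25 MYC and ribosome biogenesis genes 16 fell and 0 rose, RRS1 with -2.38 and RRP12 with -1.82 (camera adjusted p = 7.96e-05, and adjusted p = 0.285 with an estimated correlation). Of 13 YAP/TAZ targets 10 fell and 0 rose, AMOTL2 with -1.77 and AXL with -1.69 (camera adjusted p = 7.96e-05, and adjusted p = 0.285 with an estimated correlation). Of 22 ATF4 genes 13 fell and 3 rose, the amino acid transporter SLC7A5 with -3.31 and asparagine synthetase ASNS with -2.16 (camera adjusted p = 0.00323, and adjusted p = 0.312 with an estimated correlation). Adjusted over the list alone, hypoxia had 15 higher and 4 lower, ribosomal protein 21 higher, ribosome biogenesis 17 lower, YAP/TAZ 11 lower and ATF4 3 higher and 14 lower, and the other 4 lists kept their counts. Of 3 measured immune markers 2 rose, and of 3 fibroblast markers 2 rose (camera adjusted p = 0.105 and 0.0793). Without scaling beyond the library total, 1861 genes were higher and 4823 lower and the median gene moved to -0.294 (from -0.039), so changes are relative to the TMM reference. There 7 ribosomal protein genes were higher (20 with TMM), 10 hypoxia genes higher and 4 lower (15 and 3), 9 FOXO targets higher and 1 lower (12 and 0), and 1 immune marker higher (2). Without 36 h replicate 1 the counts were 1895 higher and 1926 lower, and without 36 h replicate 2 they were 1919 and 1733.

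The 4 h libraries were compared with the 0 h library to see the early response. IL24, a cytokine gene induced by STAT3, rose from 0.403 CPM to 159 ± 9.07 CPM (SD, n = 2; log2 8.61, SE 0.3, edgeR adjusted p = 4.23e-05). SOCS3, the feedback inhibitor of STAT3 signalling, rose by 4.17 (SE 0.273), the cytokine LIF by 3.18 (SE 0.266) and tenascin C (TNC) by 4.30 (SE 0.378). CCL2 went from 1 to 379 fragments, a ratio of 505 (95% interval 90.1 to 20000). Among FOXO targets, 6 of 17 fell (adjusted p = 0.177 with an estimated correlation), with PDK4 at -2.47 (SE 0.22) and CCNG2 at -1.80 (SE 0.186). In all, 491 genes were higher and 481 lower by edgeR, 417 and 397 of them by at least 2-fold; limma on log2(FPKM + 1), the planned test, called 95 and 85.

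Of 20 IL-6/STAT3 genes 9 rose and 0 fell (camera adjusted p = 7.88e-10, and adjusted p = 0.177 with an estimated correlation). STAT3 itself was not past the test (0.78, SE 0.195, edgeR adjusted p = 0.0557). Of 22 NF-kB genes 15 rose and 0 fell, TNFAIP3 by 1.86 and IL1B by 1.70 (camera adjusted p = 1.18e-16, and adjusted p = 0.177 with an estimated correlation). Of 18 matrix and protease genes 8 rose and 1 fell, the urokinase receptor PLAUR by 2.71 among them (camera adjusted p = 5.51e-09, and adjusted p = 0.177 with an estimated correlation). In that list MMP3 went from 3 to 149 fragments (ratio 66.2, 95% interval 22.2 to 325). Of 22 epithelial adhesion genes 6 rose and 0 fell, CLDN1 by 2.76 and CLDN4 by 2.53 (camera adjusted p = 6.95e-06, and adjusted p = 0.177 with an estimated correlation). Of 20 basal keratinocyte genes 7 rose and 0 fell, KRT6B by 2.94 (camera adjusted p = 4.95e-06, and adjusted p = 0.349 with an estimated correlation). Of 17 FOXO targets 6 fell and 0 rose (camera adjusted p = 1.40e-06, and adjusted p = 0.177 with an estimated correlation). Of 34 cell cycle genes 4 fell and 0 rose, the mitotic genes TTK with -1.29 and CENPE with -1.16 (camera adjusted p = 0.00305, and adjusted p = 0.501 with an estimated correlation). Adjusted over the list alone these 7 lists had 14 higher and 1 lower, 18 and 0, 11 and 1, 12 and 0, 8 and 0, 0 and 7, and 0 and 8.

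A further 8 lists passed camera at 4 h. TGF-beta targets had 6 higher and 1 lower of 16 (camera adjusted p = 9.22e-05, and adjusted p = 0.18 with an estimated correlation), ID1 rising by 1.42. The unfolded protein response had 2 higher of 19 (camera adjusted p = 6.16e-06, and adjusted p = 0.219 with an estimated correlation). MYC and ribosome biogenesis genes had 4 higher of 25 (camera adjusted p = 2.60e-05, and adjusted p = 0.177 with an estimated correlation). Interferon genes had 4 higher of 27 (camera adjusted p = 3.48e-04, and adjusted p = 0.325 with an estimated correlation). Hypoxia and glycolysis genes had 4 higher of 25, the vasodilator peptide gene ADM by 3.09 (camera adjusted p = 4.97e-04, and adjusted p = 0.501 with an estimated correlation). YAP/TAZ targets had 4 higher of 13, the tissue factor gene F3 by 2.87 (camera adjusted p = 0.00447, and adjusted p = 0.302 with an estimated correlation). Ribosomal protein genes had none past the test of 38 and cornification genes 1 higher of 14 (camera adjusted p = 0.00369 and 0.043, with adjusted p = 0.655 and 0.501 with an estimated correlation). These 8 lists, in this order and adjusted over the list alone, had 9, 9, 9, 7, 4, 5, 0 and 6 higher and 1, 0, 0, 0, 0, 0, 0 and 1 lower. Without scaling beyond the library total, 1 ribosome biogenesis gene was higher at 4 h (4 with TMM), 1 unfolded protein response gene (2) and 11 NF-kB genes (15).

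Named genes with large changes at 4 h also included TRIM40 (at least 51.7-fold higher) and KRT75 (2 to 296 fragments, ratio 197, 95% interval 54.1 to 1640). The largest falls among named genes were of lincRNA rows: linc-MANBA (42 to 1 fragments, ratio 31.5, 95% interval 5.36 to 1270), linc-FAM84B-2 with -3.99, linc-RGPD3-2 with -3.95, linc-LOC653550-22 with -3.42 and linc-POU3F4 with -3.28. The 0 h group had 1 library, so the spread came from the 4 h and 36 h pairs, and the 4 h pair differed by 10.99 times counting noise. Leaving out 4 h replicate 1 gave 1902 higher and 2386 lower genes and leaving out 4 h replicate 2 gave 1049 and 910.

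At 12 h against 0 h, the metalloprotease gene ADAMTS4 rose from 0.123 to 344 CPM (log2 11.40, SE 0.463, edgeR adjusted p = 3.52e-05) and IL24 from 0.403 to 491 CPM (log2 10.24, SE 0.322). TNC rose by 6.22 (SE 0.43), ADAM19 by 5.52 (SE 0.272) and SOCS3 by 5.00 (SE 0.296). TRIM40 was at least 298-fold, linc-DEFB105B-1 at least 219-fold and TDRD9 at least 167-fold higher. STAT3 rose by 1.22 (SE 0.22, edgeR adjusted p = 0.021). SRC was not past the test (0.32, SE 0.326, edgeR adjusted p = 0.645). By edgeR, 474 genes were higher and 187 lower, 471 and 184 of them by at least 2-fold; limma called 150 and 73.

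Of 20 IL-6/STAT3 genes 11 rose and 0 fell, HIF1A by 1.92 (camera adjusted p = 6.13e-10, and adjusted p = 0.291 with an estimated correlation). Of 22 NF-kB genes 13 rose and 0 fell, the chemokine CCL20 by 3.31 and cyclooxygenase PTGS2 by 2.72 (camera adjusted p = 4.84e-17, and adjusted p = 0.329 with an estimated correlation). Of 18 matrix and protease genes 12 rose and 0 fell (camera adjusted p = 3.97e-09, and adjusted p = 0.291 with an estimated correlation). Of 25 hypoxia and glycolysis genes 7 rose and 0 fell, PFKFB3 by 2.88 and VEGFA by 2.29 (camera adjusted p = 6.28e-10, and adjusted p = 0.359 with an estimated correlation). Of 34 cell cycle genes 4 rose and 0 fell, the S-phase genes CCNE2 by 1.62 and CDC6 by 1.31 among them (camera adjusted p = 0.00129, and adjusted p = 0.36 with an estimated correlation). Of 19 NRF2 genes 1 fell and 0 rose, GCLC with -1.58 (camera adjusted p = 0.00692, and adjusted p = 0.359 with an estimated correlation). Adjusted over the list alone these 6 lists had 13, 18, 13, 11, 9 and 0 higher and 0, 0, 2, 0, 0 and 2 lower. A further 5 lists passed camera at 12 h: FOXO targets (1 higher and 2 lower of 17), interferon (2 higher of 27), TGF-beta (3 higher of 16), and the unfolded protein response and replication histones (0 called of 19 and 16). Their camera adjusted p were 0.0412, 0.00353, 0.0388, 0.00129 and 0.00129, and adjusted p = 0.359 with an estimated correlation for the first 4 and 0.559 for the histones. For these 5, adjusted over the list alone, there were 3, 8, 4, 5 and 0 higher and 7, 0, 0, 0 and 0 lower. Without scaling beyond the library total, 2 cell cycle genes were higher at 12 h (4 with TMM), 2 TGF-beta targets (3) and 5 hypoxia genes (7).

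The receptor EPHB6 at 12 h fell with -4.13 (SE 0.576), linc-FAM84B-1 with -4.00, linc-FGF1-BP with -3.87 and the kinase CAMK2B with -3.61, and linc-CHM-2 went from 128 to 2 fragments (ratio 31.7, 95% interval 8.6 to 265). linc-ADAMTS4-AS rose from 1 to 1288 fragments (ratio 2600, 95% interval 466 to 103000), but shares its locus with ADAMTS4 and cannot be separated from it without strand. Each group had 1 library, with the spread taken from the 4 h and 36 h pairs, and leaving out 4 h replicate 1 or 2 gave 1430 or 1466 higher and 1278 or 1087 lower genes.

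**Figure D3:**
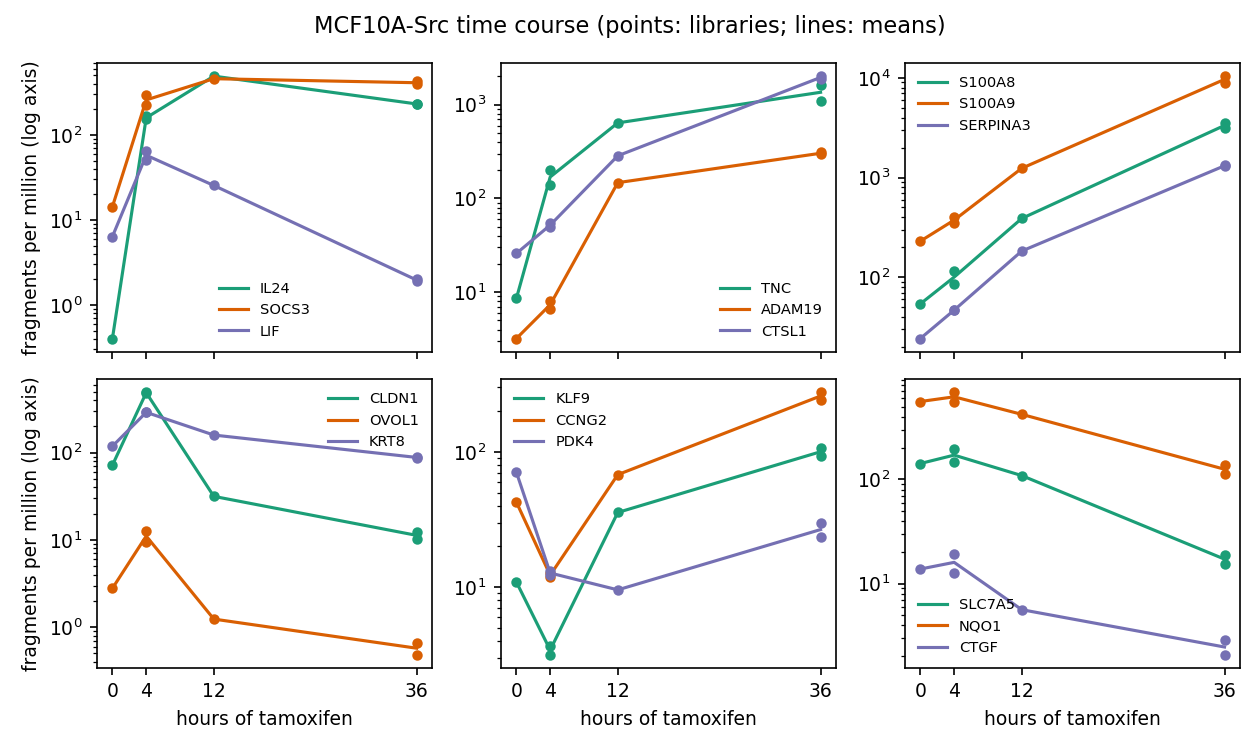
Levels (CPM, log axis) of 18 genes against hours of tamoxifen (x axis); points are libraries and lines join means. CLDN1 went from 71.8 CPM at 0 h to 486 CPM at 4 h and 11.3 CPM at 36 h, and KLF9 from 10.9 to 3.43 and 100.2 CPM.

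At 36 h against 0 h, TDRD9 was at least 1680-fold, GZMB at least 847-fold, linc-DEFB105B-1 at least 483-fold and TRIM40 at least 467-fold higher. ADAMTS4 rose by 11.47 (SE 0.457), IL24 by 9.15 (SE 0.306) and TNC by 7.30 (SE 0.441). S100A9 reached 9673 CPM from 229.6 CPM, and SERPINA3, an acute-phase protease inhibitor whose row it shares with SERPINA5, rose by 5.76 (SE 0.247). ALDH3A1, an aldehyde dehydrogenase, fell from 99.0 to 3.81 ± 0.121 CPM (SD, n = 2; log2 -4.70, SE 0.22, edgeR adjusted p = 2.53e-05). By edgeR, 1556 genes were higher and 1458 lower, 1166 and 1020 of them by at least 2-fold; limma called 1015 and 539.

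Of 18 matrix and protease genes 15 rose and 2 fell, ADAM19 by 6.56 and CTSL1 by 6.24 (camera adjusted p = 5.21e-22, and adjusted p = 0.228 with an estimated correlation). Of 22 NF-kB genes 16 rose and 0 fell, CXCL3 by 5.31 and SOD2 by 3.75 (camera adjusted p = 9.71e-13, and adjusted p = 0.26 with an estimated correlation). Of 20 IL-6/STAT3 genes 11 rose and 1 fell, SOCS3 by 4.84 (camera adjusted p = 1.01e-09, and adjusted p = 0.26 with an estimated correlation). STAT3 itself rose by 0.86 (SE 0.195, edgeR adjusted p = 0.0197). Of 25 hypoxia and glycolysis genes 14 rose and 0 fell, NDRG1 by 3.87 and VEGFA by 2.61 (camera adjusted p = 9.49e-10, and adjusted p = 0.26 with an estimated correlation). Of 38 ribosomal protein genes 20 rose and 0 fell, RPS24 by 1.10 (camera adjusted p = 1.04e-08, and adjusted p = 0.356 with an estimated correlation). Of 14 cornification genes 6 rose and 3 fell, S100A8 by 5.95 and PI3 by 2.32 (camera adjusted p = 0.0068, and adjusted p = 0.356 with an estimated correlation); the list's median was -0.08 while its mean was 1.08. Of 34 cell cycle genes 14 fell and 0 rose, E2F1 with -1.88 and PCNA with -1.39 (camera adjusted p = 4.70e-06, and adjusted p = 0.264 with an estimated correlation).

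Of 19 NRF2 genes 11 fell and 2 rose, NQO1 with -2.16 and GCLC with -2.04 (camera adjusted p = 1.12e-05, and adjusted p = 0.26 with an estimated correlation). Of 22 ATF4 genes 10 fell and 2 rose, SLC7A5 with -3.04 (camera adjusted p = 9.18e-04, and adjusted p = 0.26 with an estimated correlation). Of 13 YAP/TAZ targets 6 fell and 3 rose, ANKRD1 with -3.49 and CTGF with -2.52 (camera adjusted p = 0.00322, and adjusted p = 0.26 with an estimated correlation). Of 22 epithelial adhesion genes 4 fell and 0 rose, CLDN1 with -2.68, and of 12 mesenchymal genes 5 rose and 1 fell, SNAI1 by 2.95 and ZEB2 by 1.65 (camera adjusted p = 0.0192 and 0.0357, with adjusted p = 0.26 and 0.264 with an estimated correlation). Of 3 measured immune markers CD68 rose by 2.92 and CD14 by 1.43, and of 3 fibroblast markers DCN rose by 1.91 and FAP by 1.66 (camera adjusted p = 0.00901 and 0.00653, with adjusted p = 0.26 for each with an estimated correlation). Adjusted over the list alone, the IL-6/STAT3 list had 13 higher and 2 lower, hypoxia 17 higher, ribosomal protein 35 higher, cell cycle 21 lower, NRF2 2 higher and 12 lower, ATF4 4 and 12, YAP/TAZ 3 and 9, cornification 6 and 4 and mesenchymal 5 and 3. The matrix, NF-kB, epithelial, immune and fibroblast lists had equal counts by both adjustments.

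Of 20 basal keratinocyte genes 8 rose and 4 fell at 36 h, KRT6B by 4.16 and LAMB3 by 2.89 (camera adjusted p = 0.0197, and adjusted p = 0.425 with an estimated correlation). Of 19 unfolded protein response genes 8 rose and 0 fell (camera adjusted p = 0.00223, and adjusted p = 0.26 with an estimated correlation). Of 17 FOXO targets 5 were higher and 3 lower, not past camera (adjusted p = 0.0513), and their median of 0.40 was 0.04 without scaling beyond the library total. Of 16 TGF-beta targets 7 rose and 1 fell (camera adjusted p = 0.00322, and adjusted p = 0.26 with an estimated correlation); their median of 0.24 was -0.11 without scaling beyond the library total. The counts adjusted over the list alone were 10 and 6, 10 and 0, 6 and 3, and 7 and 1.

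EPHB6 went from 288 to 3 fragments (ratio 52.5, 95% interval 17.8 to 256) and linc-SOX14 from 169 to 3 (ratio 30.8, 95% interval 10.4 to 151), and linc-CYP4B1-AS and linc-ANKRD20A1-26 were at least 11.5-fold and 4.38-fold lower, the first not separable from CYP4B1 without strand. SRC was not past the test at 36 h against 0 h (-0.55, SE 0.283, edgeR adjusted p = 0.208). Without scaling beyond the library total, 1016 genes were higher and 3740 lower and the median gene moved to -0.429 (from -0.077). There 6 ribosomal protein genes were higher (20 with TMM), 9 hypoxia genes (14) and 4 unfolded protein response genes (8), and 28 cell cycle genes were lower (14), 11 epithelial adhesion genes (4) and 9 YAP/TAZ targets (6). Mesenchymal genes were 4 higher and 3 lower there (5 and 1 with TMM), with a median of 0.22 (0.57). Basal keratinocyte genes were 7 higher and 6 lower (8 and 4), TGF-beta targets 5 and 2 (7 and 1), IL-6/STAT3 genes 8 and 2 (11 and 1) and NRF2 genes 1 and 14 (2 and 11). Leaving out 4 h replicate 1 or 2 gave 2690 or 2878 higher and 3368 or 3003 lower genes, and leaving out 36 h replicate 2 gave 815 lower.

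**Figure D4:**
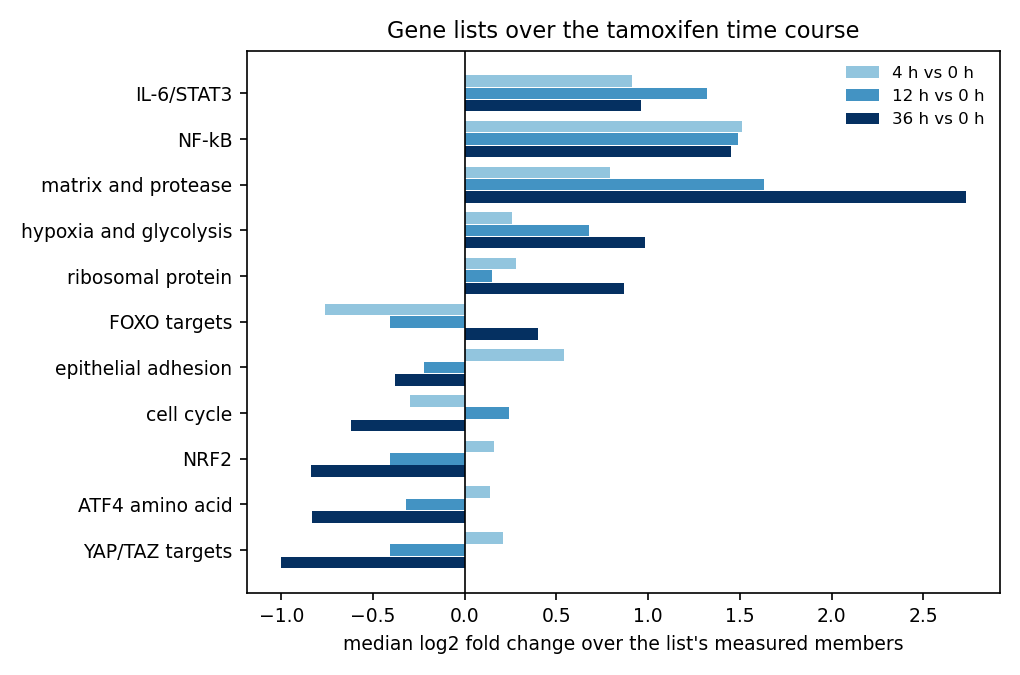
Median log2 fold change (x axis) of the measured members of 11 gene lists (y axis) at 4, 12 and 36 h against 0 h (bars, by shade). The matrix and protease median was 2.73 at 36 h, and the FOXO target median was -0.76 at 4 h; bars carry no error and use TMM scaling.

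The fold changes of the 2 experiments were set side by side, each fitted on its own. The question was whether LINC00520 over-expression moved the genes that change over the tamoxifen time course. Across 12352 genes tested in both, the 36 h against 0 h and LINC00520 fold changes had a Pearson r of -0.021 and a Spearman rho of -0.073; genes are not independent replicates, and 4 such relations were computed. Of 1127 genes higher at 36 h, 279 were higher and 400 lower with LINC00520 (289 and 279 for independent lists), with a median of -0.03 and camera adjusted p = 0.121. Of 1181 genes lower at 36 h, 402 were higher and 373 lower (303 and 292 for independent lists), with a median of 0.02 and camera adjusted p = 0.463. The numbers for independent lists assume that a call in 1 experiment is unrelated to a call in the other. Both directions lay above them among these lower genes, so an excess over them alone does not show a shared direction. The 12 h fold changes had an r of 0.267, and of 149 genes lower at 12 h 106 were lower and 18 higher with LINC00520 (37 and 38 for independent lists; median -0.34, camera adjusted p = 9.43e-20, and adjusted p = 0.16 with an estimated correlation). Of 281 genes higher at 12 h, 108 were higher and 85 lower (72 and 70 for independent lists; camera adjusted p = 0.0765). For 36 h against 4 h r was -0.113 and the sets ran the opposite way. The 36 h against 4 h change is the difference between the 36 h and 4 h changes against 0 h. Its relation is therefore not separate from theirs. The comparisons against 0 h in turn share the 1 library at 0 h. Of 2200 higher genes 451 were higher and 772 lower with LINC00520 (564 and 545 for independent lists). Of 2867 lower genes 1012 were higher and 607 lower (734 and 710 for independent lists). Their camera adjusted p were 0.0268 and 0.0284, and adjusted p = 0.235 for each with an estimated correlation. For 4 h against 0 h r was 0.146. Of 371 higher genes 178 were higher and 77 lower with LINC00520 (95 and 92 for independent lists). Of 312 lower genes 136 were lower and 55 higher (77 and 80 for independent lists). Their camera adjusted p were 0.00136 and 0.0209, with adjusted p = 0.16 and 0.235 with an estimated correlation. The overlap counts depended on the processing: with limma on log2(FPKM + 1) there were 160 genes higher in both, 123 lower in both, 235 higher at 36 h and lower with LINC00520, and 108 the other way round. Without scaling beyond the library total these were 173, 802, 238 and 1084.

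The authors' deposited table of Cuffdiff calls (q under 0.05) held 975 genes higher and 923 lower with LINC00520, of which 1778 among the genes tested here were called in the same direction by edgeR and 0 in the opposite one. For 36 h against 4 h the authors' deposited table held 2321 higher and 2577 lower, with 4265 called in the same direction and 1 opposite. Against 0 h it held 955 and 615 at 4 h, 772 and 470 at 12 h and 1681 and 1242 at 36 h, with 670, 505 and 2151 shared in direction. In the authors' deposited table LINC00520 had log2 fold changes of 9.19 with over-expression (q = 0.00895), 9.37 for 36 h against 4 h, 4.29 for 12 h against 0 h and 8.83 for 36 h against 0 h (q = 0.000829 for each), and -0.54 for 4 h against 0 h (q = 1).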

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

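The tests of scaling, of left-out libraries and of HBB were chosen after the result was seen; the test of transduction was set out before. Named genes called in opposite directions at 4 h and at 36 h against 0 h were singled out. The values of 36 h against 4 h by edgeR given here size the difference; the choice of genes required it, so they are no separate test. CLDN1, a tight junction gene, was at 71.8 CPM at 0 h, 486 at 4 h, 31.5 at 12 h and 11.3 at 36 h (difference -5.44, SE 0.191). LIF was at 6.38, 57.7, 25.4 and 1.96 CPM (difference -4.86), OVOL1 at 2.79, 11.1, 1.24 and 0.574 CPM (-4.32), and ID3 at 13.8, 42.7, 16.7 and 6.78 CPM (-2.64). The PI3K subunit PIK3R1 was at 284, 158, 176 and 586 CPM (1.89), and the FOXO targets KLHL24 at 60.5, 20.2, 34.6 and 143 CPM (2.82), CCNG2 at 42.5, 12.3, 67.8 and 259 CPM (4.40) and KLF9 at 10.9, 3.43, 35.6 and 100.2 CPM (4.86). In all, 75 genes were called in opposite directions at the 2 times, 34 higher at 4 h and lower at 36 h and 41 the reverse; the 0 h group had 1 library, which both comparisons against 0 h share.

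Cell cycle genes were higher and ribosomal protein genes lower with LINC00520. For the cell cycle genes the smallest median over 4 scalings was 0.52. These scalings moved the median gene so little (-0.009 to 0.001) that they could not test library scaling. Quantile normalization left the cell cycle median at 0.50 with 34 of 34 higher by limma. Only this last result argues against scaling for the cell cycle genes. For the ribosomal protein genes scaling is left open, since quantile normalization brought their median to -0.07 with 23 of 38 lower; the authors' deposited values kept a median of -0.20, with 0 of 38 called. A deviating library is also argued against, since 34 cell cycle genes were called higher and 37 or 38 of the 38 ribosomal protein genes lower whichever library was left out. Leaving out a library cannot show a deviating culture, since nothing in the labels says that replicates came from separate cultures. A difference between the transduced and untransduced cultures as such was therefore not tested. An effect of transduction, or of any introduced RNA, and an effect of LINC00520 itself cannot be told apart. The 2 control lincRNA libraries that would separate them were not analysed here. A further 7 libraries whose condition names match no label were not used.

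HBB had 28 fragments in the LINC00520 libraries and 3 in the untransduced ones. RNA from red blood cells is argued against, but on few fragments. HBA1 and HBA2 together had 4 fragments in the LINC00520 libraries and 7 in the untransduced ones (ratio 1.08, 95% interval 0.233 to 4.26). How fragments that match both genes were counted was not given, so their row may be undercounted. A globin element of the vector may have given the 28 fragments, but this and induction of the gene by LINC00520 cannot be told apart without the control lincRNA libraries.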

How the results depend on the processing

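DESeq2, edgeR's own count filter, median-ratio and upper-quartile factors and no scaling beyond the library total were chosen after the result was seen, as were the overlap counts. The alternatives for the control lincRNA were not run, since its libraries were not analysed here, and fitting only the 2 groups of the over-expression comparison was the fit already made. LINC00520 with over-expression and for 36 h against 4 h or 0 h kept its direction and its call under every alternative run. The correlation of the experiments (-0.021) and the medians of the genes called at 36 h (-0.03 and 0.02) each moved by less than 0.1. That margin is larger than the values themselves, so it does not show that their signs were kept. Of 8794 values under alternatives of 469 results of named genes other than LINC00520, 7988 kept direction and side of the threshold, 672 were no longer past it, 130 newly passed it and 4 changed sign. None of the 4 had passed the test: SRC with over-expression went from -0.0163 to 0.065 as each replicate was left out, STAT3 for 36 h against 4 h was -0.17 without scaling and went from -0.0124 to 0.172 as each replicate was left out, and the FIP1L1 and PDGFRA row for 36 h against 0 h was -0.023 without scaling. LINC00520 at 4 h against 0 h also changed sign, not past the test in either fit, to 0.11 after quantile normalization. LINC00520 at 12 h was 2.00 with limma and a pseudocount of 1, 0.76 with 5, 2.00 without the trend and 2.02 after median-ratio rescaling, not past the test.

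The cause was not tested for the following changes, unless named. Higher genes at 4 h against 0 h were 95, 78 and 89 by limma with pseudocounts of 1, 0.1 and 5, 86 without the trend, 143 after quantile normalization and 97 after median-ratio rescaling; 1234 with no filter, where more genes are tested, and 955 by the authors. The lower genes were 85, 80, 93, 78, 124 and 88 by those limma settings and 1560 with no filter. At 12 h, higher genes were 150, 174, 124, 150, 268 and 155 by limma, 1026 with no filter and 772 by the authors, and lower genes 73, 78, 83, 69 and (median-ratio) 74 by limma, 691 with no filter and 470 by the authors. At 36 h against 0 h, higher genes were 1015, 905 and (without the trend) 1002 by limma and 1016 without scaling; lower genes were 539, 415, 560, 515, 938 and 556 by limma, 2842 with no filter and 3740 without scaling. For 36 h against 4 h, 1861 were higher and 4823 lower without scaling, and with over-expression the authors called 975 and 923. With each replicate left out in turn, counts of higher and lower genes ranged from 1895 to 3642 and 1733 to 3718 for 36 h against 4 h, 509 to 1902 and 592 to 2386 at 4 h, 541 to 1466 and 232 to 1278 at 12 h, 1108 to 2878 and 815 to 3368 at 36 h, and 2473 to 3177 and 2368 to 3134 with over-expression. Shared calls with the authors were 100 at 4 h, 132 at 12 h and 1216 at 36 h by limma. With an estimated correlation camera called 0 of 27 lists in every comparison, against 15, 9, 15, 11 and 17 at the preset one. The order is over-expression, 36 h against 4 h, then 4, 12 and 36 h. At an unadjusted p under 0.05 the estimated correlation gave 9, 4, 7, 3 and 3 lists. At the adjusted threshold fry called 18, 14, 6, 9 and 19. In the simulations camera with an estimated correlation gave changed sets an unadjusted p of 0.00271 to 0.023. Its 0 calls are therefore weak evidence against the lists. Overlaps with LINC00520 calls at 36 h, by those 6 limma settings, were 160, 144, 162, 152, 171 and 166 higher in both, 123, 89, 128, 119, 214 and 127 lower in both, 235, 198, 241, 226, 251 and 241 higher at 36 h and lower with LINC00520, and 108, 86, 99, 99, 226 and 114 the other way; without scaling 173, 802, 238 and 1084; by the authors' calls 120, 153, 190 and 166; lower in both were 611 with no filter, and 247 by DESeq2, which gave 260 lower at 36 h and higher with LINC00520. With the replicate number as a block, 2756 genes were higher and 2744 lower with LINC00520 (log2 8.07 for LINC00520 itself) and 3080 and 3373 for 36 h against 4 h (7.20), and with only the 4 h and 36 h libraries 2951 and 3215; same-numbered libraries correlated at -0.028, -0.041 and 0.078, and the number is only a name. With 12.6 M fragments in the shallowest library and 1 library at 0 h and 12 h, simulated 2-fold changes were recovered in 12% to 54% of genes in the time course. Those simulations changed 50 genes at each size, fewer than edgeR called in the data.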

Other observations

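The lincRNA rows below were chosen after their values were seen. Among lincRNA rows at 10 CPM or more at 36 h, linc-PCDH7-6 (chromosome 4, 28312616 to 28626029) went from 0.099 CPM at 4 h to 23.7 CPM at 36 h (log2 7.91, SE 0.396, edgeR adjusted p = 1.32e-05) and linc-NAV3 (chromosome 12, 77718277 to 77979815) from 0.0637 to 15.4 CPM (log2 7.70, SE 0.579). linc-FAM19A1-2 (7.06, SE 0.328), linc-RP1-1 (6.40, SE 0.362), linc-C2orf27B-7 (6.28, SE 1.14) and linc-MRPL32-2 (6.23, SE 0.357) followed LINC00520 in this order. linc-STC1-AS reached 1.72, 59.0, 1253 and 3327 CPM at 0, 4, 12 and 36 h, and linc-GK-AS 12.1, 5.05, 51.1 and 340 CPM, but both are antisense rows whose fragments cannot be separated from their partner genes without strand. By edgeR 771 of 3990 lincRNA rows were higher and 434 lower at 36 h against 4 h, and 234 of 1781 were higher and 446 lower with LINC00520 over-expression, 10 and 18 of these by at least 2-fold.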
